A study of Drosophila melanogaster with 6 samples.

How the data were processed

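RNA from wing imaginal discs of Drosophila melanogaster was profiled on Affymetrix Drosophila Genome 2.0 arrays, 3 arrays from w1118 discs and 3 from kdm5 mutant discs, each from about 60 discs dissected at 96 h AED. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cDNA was prepared from it for hybridization. The values used are those of the deposited series matrix, which the authors supplied as normalized log2 signal per probe set. The submitters' processing notes name GCOS, Affymetrix Expression Console, PLIER and GCRMA without versions or order, and which of them made the deposited log2 values is not given in the sources used here. The scanner files were not used here, so no detection call or background level per probe set was at hand. Minimum and maximum values were alike on the 6 arrays (2.21 to 2.30 and 14.41 to 14.48), as were the medians (4.41 to 4.44).

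The 6 samples were grouped by the titles in the labels, which also number the biological replicates. No label states that replicates of different genotype share a number for a reason, and no scan or hybridization batch is given, so a batch that follows genotype is not excluded. Whether the 3 replicates of a group came from separate crosses is not stated, and p-values measure the spread between these samples. No 2 arrays held more than 1 identical value over 18769 probe sets. Correlations of log2 values were 0.998 to 0.999 within a genotype and 0.989 to 0.99 between genotypes, across probe sets, which are not independent replicates. The first principal component of the 9385 probe sets above the median level held 88.2% of the variance and separated the genotypes.

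Of 18952 probe sets 183 are control probe sets of the manufacturer, which were left out of the tests, leaving 18769. GEO's platform annotation gave 1 gene symbol for 13647 of these, several for 402 and none for 4720; a probe set with several named no gene, and genes named here only through such probe sets were not analysed. Symbols were updated through the gene identifier for 13544 probe sets with the gene table of assembly GCF_000001215.4 Release 6, which was also used for gene order. The series names no genome build, so no coordinates are given. Of the 11982 genes, 1094 had more than 1 probe set, and a gene is represented by the probe set with the highest mean over the 6 arrays.

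Each probe set was tested with limma 3.58.1 (lmFit and eBayes without trend, R 4.3.3) on the deposited log2 values, with genotype as the only term, two-sided, and Benjamini-Hochberg adjustment over all 18769 probe sets at a threshold of 0.05. The residual degrees of freedom were 4. A size threshold of 2-fold was reported beside it. Changes are mutant minus wild type on the log2 scale, with the moderated SE of limma, and means carry the SD of 3 arrays. For Kdm5 an exact two-sided permutation test was added.

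Gene lists were tested with limma's camera on 1 probe set per gene, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists of at least 3 measured genes, and again with an estimated correlation. Beside it limma's fry was run, which asks whether the members of a list change at all, not whether they change more than other genes. The lists cover antioxidant enzymes, glutathione S-transferases, cytochrome P450s, Foxo targets, the mitochondrial electron transport chain, mitochondrial and cytosolic ribosomes, ribosome biogenesis, the proteasome, heat shock proteins, DNA replication and the cell cycle, wing patterning, Notch targets, homeotic genes, regulators of histone methylation, the ecdysone response, immune effectors, JNK stress genes and cell death. Marker lists covered germline and testis, haemocytes, fat body, trachea, myoblasts, muscle, salivary gland, gut, neurons and glia, and cuticle. They were included because such cells may adhere to dissected discs or form part of them. Male dosage compensation genes, which bear on sex and not on adhering cells, formed a further list.

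The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule names Kdm5 and the called histone methylation regulators, the 12 genes of the largest rise and of the largest fall whose arrays do not overlap and whose higher mean lies above the median level, and of each list up to 4 members of smallest p, or the 2 brightest where none was called. Genes in counts of 5 or fewer that the rule leaves out, and the neighbours, were named after their values were seen. A "call" is an adjusted p under 0.05.

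Alternatives were a term for the replicate number, quantile normalization, centring on each array's median, a filter on dim probe sets, a trended and robust prior, array weights, 1 probe set per gene, the mean of a gene's probe sets, an estimated correlation for the lists, and each array left out in turn. Centring on the hybridization and polyadenylated spike-in controls was added after the data were seen.

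The limma, camera, neighbour, family and correlation tests were tested on simulated data, for the first pair drawn with the levels and spread of the real probe sets. Of 50 probe sets changed by 0.25, 0.5, 1 or 2 log2 units each, limma recovered 2, 80, 100 and 100% over 18769 probe sets in the simulated comparison of mutant with wild type, with 2 false calls among 143. With no change planted it made 0 calls. The data gave 3439 calls against 143 in the simulation, so the adjustment differs and these shares do not give the recovery in the data. Of 20 lists of 20 genes shifted by 0.2 camera found 20, and 0 of 80 unshifted lists. The simulated genes were drawn independently, so this cannot show how often the preset correlation passes unshifted lists whose genes vary together. Figures were drawn with matplotlib 3.10.9.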

Results

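RNA was measured from wing imaginal discs, the epithelial sacs of the larva that form the adult wing and part of the thorax. Discs were dissected in the third larval instar at 96 h AED from w1118 flies, used as wild type, and from flies mutant for kdm5. Each group had 3 biological replicates of about 60 discs, and each replicate was hybridised to 1 Drosophila Genome 2.0 array. Kdm5, also called lid (little imaginal discs), encodes a demethylase of histone H3 methylated at lysine 4. The comparison of the groups asks which transcripts differ in the mutant discs. No wild type of the mutant's own background was included, so strain differences cannot be told apart from effects of the mutation in any change below. The median log2 level of the arrays lay between 4.41 and 4.44, and the number of arrays, 3 per group, limits the precision of every value below.

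The Kdm5 transcript was nearly lost from the mutant discs. Its log2 level was 10.08 ± 0.08 in wild type and 4.29 ± 0.51 in the mutant (SD, n = 3 each), and the mutant arrays gave 4.67, 3.70 and 4.49. The fall was 55.3-fold, a log2 change of -5.79 ± 0.23 (SE, adjusted p = 6.18e-06, limma with Benjamini-Hochberg adjustment). An exact two-sided permutation test of the difference gave p = 0.1, the smallest value that 3 arrays against 3 allow. The mutant mean lay below 4.44, the median level over all probe sets and arrays, so the size of this fold depends on the background of the array. The gene is represented by 1 probe set, and the place of the lesion relative to it is not given in the sources used here.

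The kdm5 mutant discs gained transcripts of several genes that wild type discs held at very low levels, and lost others almost completely. Zip102B, a zinc transporter, rose from 4.63 ± 0.04 to 10.39 ± 0.02, and ry, which encodes xanthine dehydrogenase, rose from 3.22 ± 0.09 to 8.79 ± 0.07 (log2, SD, n = 3 each). Gyc89Da, a soluble guanylyl cyclase, fell from 9.40 ± 0.17 to 3.30 ± 0.12, and GstD3, a glutathione S-transferase, fell by 4.97 ± 0.14 (SE). Most other changes were small. Of 18769 probe sets tested, 3439 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 1593 higher and 1846 lower in the mutant, and their median absolute log2 change was 0.39. Of these, 481 changed at least 2-fold, 188 higher and 293 lower. Counted by gene, 2600 of 11982 named genes changed, 1170 higher and 1430 lower, and 351 of them at least 2-fold, 133 higher and 218 lower. In all 3439 the arrays of the 2 groups did not overlap. Over all probe sets 36.1% did not overlap, against 10% given by chance for 3 arrays against 3. Lower calls made up 53.7% of the calls with the arrays as deposited, 49.6% with quantile normalization, 50.7% with each array centred on its median, 34.2% with each array centred on its polyadenylated spike-in controls and 12.8% with each centred on its hybridization spike-in controls. The spike-in centrings moved the median log2 change of all probe sets from 0.01 to 0.09 and 0.19, a shift that lowers the share of lower calls by itself. Higher calls numbered 1037 without mutant replicate 1 and 1020 without mutant replicate 2.

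**Figure D1:**
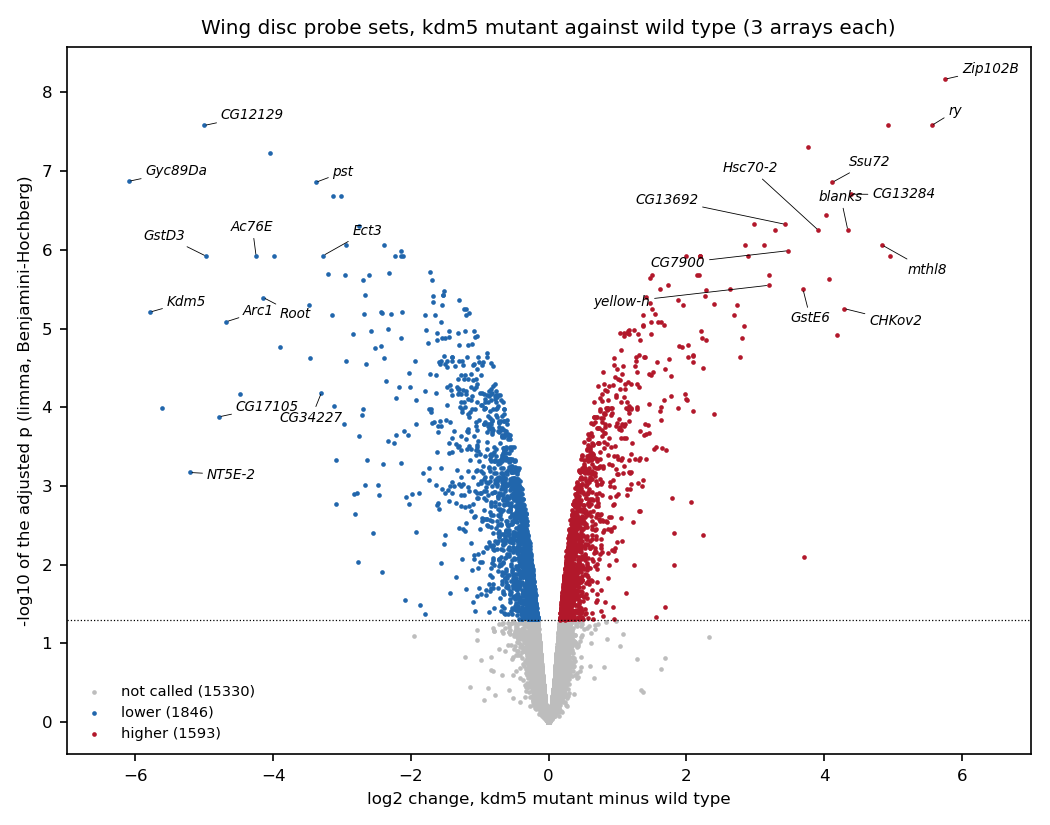
Log2 change of each probe set, kdm5 mutant minus wild type, against the negative log10 of its adjusted p (limma, 3 arrays per group); the dotted line marks an adjusted p of 0.05, red and blue points passed it, and the 24 genes of the largest rises and falls are named. Changes of over 5 log2 units are seen on both sides, from -6.10 for Gyc89Da to 5.76 for Zip102B.

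Among the 12 genes of the largest rise, Zip102B and ry gained 5.76 ± 0.05 and 5.56 ± 0.07 (log2 change ± SE), followed by the receptor gene mthl8 with 4.84 ± 0.12 and CG13284 with 4.39 ± 0.08. The gene blanks, which encodes an RNA-binding protein known from the testis, rose by 4.35 ± 0.10, CHKov2 by 4.29 ± 0.17 and the phosphatase gene Ssu72 by 4.12 ± 0.07. The chaperone gene Hsc70-2 rose by 3.92 ± 0.09, GstE6 by 3.69 ± 0.13, CG7900 by 3.48 ± 0.09, CG13692 by 3.44 ± 0.07 and yellow-h by 3.20 ± 0.11. The adjusted p of these 12 genes ran from 6.77e-09 to 5.58e-06 (limma). In ry, mthl8, Ssu72, Hsc70-2, CG7900 and yellow-h the wild type level lay below the median level of all probe sets, and in Zip102B, blanks and CHKov2 just above it (4.63, 4.70 and 4.62), so their fold depends on the background of the array.

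The 12 largest falls began with Gyc89Da at -6.10 ± 0.10 and Kdm5 itself. NT5E-2, a 5'-nucleotidase, fell by 5.21 ± 0.55, with a spread among the wild type arrays (SD 1.26, n = 3) far above that of most genes. CG12129 fell 32.1-fold, GstD3 by 4.97 ± 0.14 and CG17105 by 4.79 ± 0.36. Arc1, which encodes a capsid-forming protein related to retrotransposon Gag, fell by 4.68 ± 0.20, and the adenylyl cyclase gene Ac76E by 4.25 ± 0.12. Root, which encodes rootletin of the ciliary rootlet, fell by 4.14 ± 0.15, pst by 3.38 ± 0.06, CG34227 by 3.30 ± 0.21 and Ect3 by 3.27 ± 0.09. Their adjusted p lay between 2.63e-08 for CG12129 and 0.000676 for NT5E-2 (limma). Mutant levels of Gyc89Da, Kdm5, NT5E-2, Ac76E and Root lay below the median of all probe sets, and those of CG12129, CG17105 and Ect3 just above it (4.48, 4.69 and 4.63), so their fold too depends on the background.

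Several markers of tissues that lie next to the discs in the larva fell. Of 13 measured genes of the salivary gland list, 7 fell and none rose, 8 lower when adjusted over the list alone. The glue protein genes Sgs3, Sgs7, Sgs4 and Sgs8 fell by 3.08 ± 0.39, 2.97 ± 0.24, 2.66 ± 0.30 and 2.48 ± 0.28 (log2 change ± SE), Sgs3 from a wild type level of 10.08 ± 0.90 (SD, n = 3). The median of the list was -0.83 (limma camera, adjusted p = 0.000794; adjusted p = 0.541 with an estimated correlation), -0.31 without wild type replicate 1 and -2.52 over the 8 members kept by the filter on dim probe sets. Of 12 fat body genes 6 fell, also 6 when adjusted over the list alone, with a median of -1.31 (camera, adjusted p = 0.00263; adjusted p = 0.541 with an estimated correlation). Among them were Obp99b at -2.83 ± 0.34, Fbp1, a receptor for storage proteins, at -1.82 ± 0.19, Obp99a at -1.41 ± 0.07 and the fatty acid synthase gene FASN1 at -1.40 ± 0.08. Centred on the hybridization spike-in controls the medians of these lists read -0.65 and -1.13. Within wild type these markers spread widely: Sgs3 read 11.11, 9.71 and 9.42 on the arrays of replicates 1, 2 and 3, and Obp99b 10.03, 8.50 and 9.09.

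Genes of differentiated muscle fell in 9 of 15 cases and rose in 1, Act87E at 0.28 ± 0.06, with 9 lower and 2 higher when adjusted over the list alone. Mlc1, a myosin light chain, changed by -1.37 ± 0.16, TpnC73F, a troponin C, by -1.30 ± 0.08 (-0.61 with its probe sets averaged), Tm2, a tropomyosin, by -1.27 ± 0.12 and the paramyosin gene Prm by -0.89 ± 0.13 (log2 change ± SE). The median of the muscle list was -0.59 (limma camera, adjusted p = 0.0148; adjusted p = 0.541 with an estimated correlation). Of 19 haemocyte genes 9 fell and 2 rose, 10 and 2 when adjusted over the list alone, with a median of -0.29 (camera, adjusted p = 0.00708; adjusted p = 0.541 with an estimated correlation). The prophenoloxidase genes PPO1 and PPO2 fell by 1.59 ± 0.21 and 1.56 ± 0.13, the collagen gene Col4a1 by 0.92 ± 0.11 and NimB1 by 0.65 ± 0.06, while Ppn and eater rose by 0.26 ± 0.06 and 0.57 ± 0.16. Germline and testis genes fell in 8 of 31 cases, also 8 when adjusted over the list alone, with a median of -0.13 (camera, adjusted p = 0.00439; adjusted p = 0.541 with an estimated correlation), or -0.07 without wild type replicate 2. The germline genes bam, piwi, tej and Mst87F fell by 0.91 ± 0.15, 0.59 ± 0.08, 0.43 ± 0.06 and 0.40 ± 0.06, though only 5 of the 31 lay above the median level on every mutant array. With only probe sets above the median level kept, the haemocyte and germline medians read -0.33 over 15 members and -0.27 over 6, and the lists no longer passed (camera, adjusted p = 0.0581 and 0.115, and over all alternatives 3.28e-05 to 0.541 and 0.00185 to 0.541). Centred on the hybridization spike-in controls the germline median read 0.05 and tej and Mst87F were not called, while the other lists named here kept lower medians. Lower haemocyte calls numbered 5 without wild type replicate 1, mutant replicate 2 or mutant replicate 3, and lower germline calls 5 without wild type replicate 2, wild type replicate 3 or mutant replicate 1. Act87E lost its call without wild type replicate 1 or mutant replicates 1 or 2 (0.0556 to 0.0649) and Ppn without wild type replicates 1 or 2 or mutant replicates 1, 2 or 3 (0.0516 to 0.0726), limma adjusted p in parentheses. eater lost its call without wild type replicates 2 or 3 or mutant replicates 1 or 2 (0.0821 to 0.14), limma adjusted p in parentheses.

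**Figure D2:**
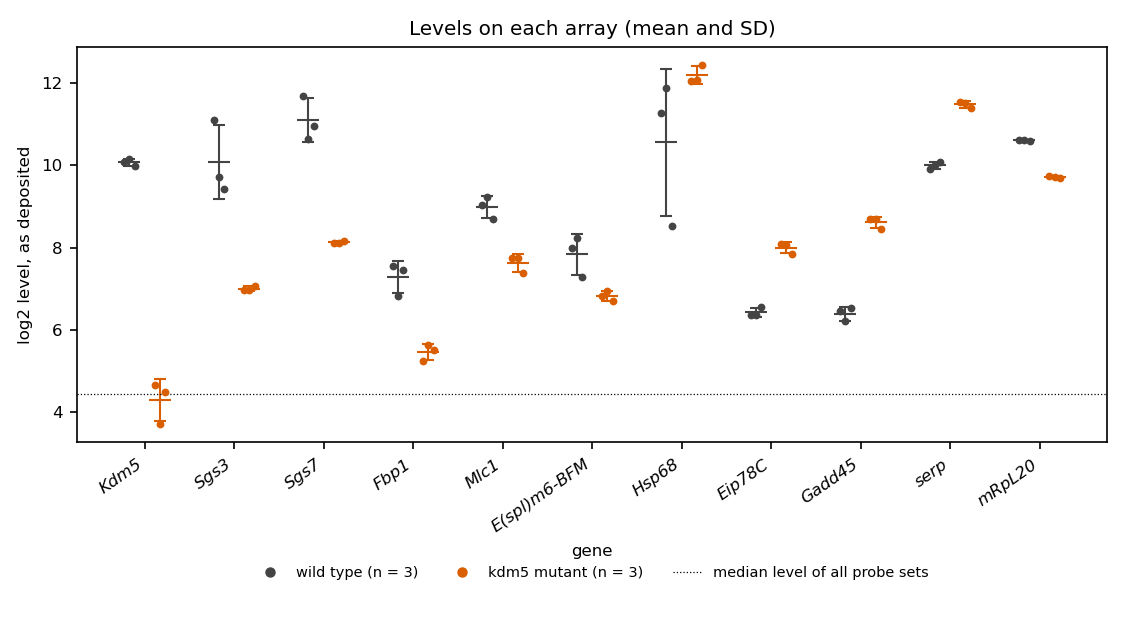
Log2 level of 11 genes on each array, wild type in grey and kdm5 mutant in orange; bars give the mean and SD of 3 arrays and the dotted line the median level of all probe sets, 4.44. Kdm5 and the salivary gland, fat body and muscle markers lie lower on every mutant array, Sgs3 is highest on the array of wild type replicate 1 at 11.11, and Hsp68 spans 8.53 to 11.88 within wild type.

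Genes of trachea, myoblasts, gut, neurons and cuticle were counted in the same way. Of 9 tracheal genes 3 rose and 1 fell, 3 and 2 when adjusted over the list alone. The chitin deacetylase genes serp and verm rose by 1.48 ± 0.07 and 0.96 ± 0.05 and Osi7 by 0.31 ± 0.06, while Gasp changed by -0.25 ± 0.06 and was not called under either spike-in centring. Gasp lost its call without wild type replicates 2 or 3 or mutant replicates 1 or 2 (0.0573 to 0.0774) and Mal-A1 without wild type replicates 1, 2 or 3 or mutant replicates 1 or 3 (0.0712 to 0.0943), limma adjusted p in parentheses. Among 8 genes of the adepithelial myoblasts, the muscle precursors attached to the disc, Nplp2 fell by 1.34 ± 0.17 and Ama rose by 0.36 ± 0.06, the same count when adjusted over the list alone. Of 24 gut genes the mannosidase gene LManII fell by 2.58 ± 0.12, the single call when adjusted over the list alone. Mal-A1, at 0.24 ± 0.06, was called higher over all probe sets. Of 13 neuronal and glial genes 3 fell, also 3 when adjusted over the list alone. ChAT, which makes acetylcholine, fell by 0.61 ± 0.06, the calcium channel gene cac by 1.20 ± 0.27 and futsch by 0.22 ± 0.05. ChAT lay below the median level of all probe sets in both genotypes and cac in the mutant, so the size of these changes depends on the background, and cac read -0.60 with its probe sets averaged. cac lost its call without wild type replicate 1 or mutant replicates 1 or 2 (0.0646 to 0.0702) and futsch without wild type replicate 1 or mutant replicate 2 (0.0683 to 0.0835), limma adjusted p in parentheses. Of 102 cuticle protein genes 21 fell and 6 rose, 21 and 7 when adjusted over the list alone. Cpr65Ec, Cpr78E and Cpr67Fa2 fell by 1.28 ± 0.08, 1.11 ± 0.07 and 1.07 ± 0.08 and Cpr49Ah rose by 1.40 ± 0.07. None of these 5 lists passed as a group (limma camera, adjusted p from 0.223 for trachea and cuticle to 0.938 for gut). The cuticle list passed with the arrays centred on the polyadenylated or the hybridization spike-in controls (camera, adjusted p = 0.0423 and 0.0157, and up to 0.608 over all alternatives), and 3 cuticle genes rose without wild type replicate 1 or mutant replicate 3. Of the male dosage compensation genes only msl-2 was measured, at -0.67 ± 0.19 (adjusted p = 0.0551, limma), and it was called under 8 of 16 alternatives, among them without wild type replicate 2 (limma adjusted p = 0.042) or mutant replicate 3 (0.015), with a range of 0.015 to 0.156 over all alternatives.

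Some genes of mitochondria and growth fell, most of them by small amounts. Of 69 mitochondrial ribosomal protein genes 24 fell and 1 rose, 35 and 1 when adjusted over the list alone, with a median of -0.15 (limma camera, adjusted p = 1.45e-06; adjusted p = 0.541 with an estimated correlation). The largest fall within this list was that of mRpL20, at -0.89 ± 0.05, and mRpS18C, mRpS24 and mRpS17 changed by -0.44 ± 0.05, -0.43 ± 0.05 and -0.42 ± 0.05 (log2 change ± SE), while mRpL14 rose by 0.24 ± 0.05. Of 64 nuclear genes of the electron transport chain and ATP synthase 14 fell and 1 rose, 15 and 1 when adjusted over the list alone, with a median of -0.08 (camera, adjusted p = 0.00336; adjusted p = 0.606 with an estimated correlation). UQCR-11 of complex III changed by -0.98 ± 0.11, ND-B14.5B of complex I by -0.36 ± 0.05 and ATPsynE by -0.33 ± 0.05, and ATPsynepsilonL rose by 2.24 ± 0.13. Of 28 genes of ribosome biogenesis and Myc-driven growth 8 fell, also 8 when adjusted over the list alone, among them kra at -0.43 ± 0.05, Non1 at -0.27 ± 0.06, the fibrillarin gene Fib at -0.25 ± 0.05 and Polr1A at -0.24 ± 0.05. The median of that list was -0.11 (camera, adjusted p = 0.00513; adjusted p = 0.541 with an estimated correlation). Of 26 DNA replication and cell cycle genes 8 fell and 1 rose, 11 and 1 when adjusted over the list alone, with a median of -0.08 (camera, adjusted p = 0.00336; adjusted p = 0.541 with an estimated correlation). The replication helicase genes Mcm5 and dpa changed by -0.40 ± 0.05 and -0.23 ± 0.05, fzy by -0.32 ± 0.05 and cyclin B by -0.26 ± 0.05, and CycD rose by 0.21 ± 0.05.

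Lower calls in these lists became fewer with 1 array left out, whichever it was, and with the arrays centred on spike-ins, which shifts all probe sets. With quantile normalization and with each array centred on its median all 4 lists passed (limma camera, adjusted p up to 0.00627 and 0.00733), with 25 and 22 mitochondrial ribosome genes lower. With each array left out in turn all 4 lists still passed with the preset correlation (limma camera, adjusted p up to 0.0215), and the mitochondrial ribosome median ran from -0.13 to -0.16. Centred on the hybridization spike-in controls, the medians of the mitochondrial ribosome, electron transport, ribosome biogenesis and cell cycle lists read 0.03, 0.10, 0.07 and 0.10, each still below the median of all genes, and the last 3 lists lost their calls (limma camera, adjusted p = 0.266, 0.252 and 0.0974, and over all alternatives from 0.00162, 0.00218 and 0.00185 to 0.606, 0.541 and 0.541). With the polyadenylated spike-ins electron transport and ribosome biogenesis also lost their calls (camera, adjusted p = 0.0886 and 0.078), and 7 mitochondrial ribosome genes were called lower. Under either centring ATPsynE, ND-B14.5B, Non1, Fib, Polr1A, dpa, fzy and CycB were no longer called, nor was Mcm5 with the hybridization spike-ins. With its probe sets averaged fzy read -0.18 and lost its call (limma adjusted p = 0.0629). Without wild type replicates 1, 2 and 3 and mutant replicates 1, 2 and 3, in that order, the lower calls numbered 14, 20, 17, 17, 14 and 16 for the mitochondrial ribosome and 5, 6, 4, 5, 6 and 3 for electron transport. They numbered 2, 7, 4, 3, 1 and 3 for ribosome biogenesis and 4, 7, 4, 3, 4 and 6 for the cell cycle. mRpL14 lost its call without wild type replicates 1 or 2 or mutant replicates 1 or 2 (0.0546 to 0.0665) and Non1 without mutant replicate 2 (0.0616), limma adjusted p in parentheses. Fib lost its call without wild type replicate 1 or mutant replicates 1 or 2 (0.0536 to 0.0683) and Polr1A without wild type replicate 1 or mutant replicates 2 or 3 (0.0513 to 0.0634), limma adjusted p in parentheses. dpa lost its call without wild type replicate 1 or mutant replicate 1 (0.0591 to 0.0683) and CycD without wild type replicates 1 or 3 or mutant replicates 1 or 2 (0.0642 to 0.0878), limma adjusted p in parentheses.

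Of the cytosolic ribosomal protein and proteasome genes few were called. Of 34 ribosomal protein genes measured, the paralogue gene RpS19b rose by 1.62 ± 0.12 and RpS10a by 0.23 ± 0.06, and RpL34a and RpS5b changed by -0.26 ± 0.05 and -0.41 ± 0.10 (log2 change ± SE); the count adjusted over the list alone was also 2 higher and 2 lower. Of 40 proteasome genes Prosalpha6, Rpn1 and Prosalpha4 rose by 0.34 ± 0.05, 0.29 ± 0.05 and 0.22 ± 0.05 and Rpt3R, a paralogue of a base subunit, fell by 1.60 ± 0.13, again 3 and 1 when adjusted over the list alone. Neither list passed (limma camera, adjusted p = 0.638 and 0.321). RpS10a lost its call without wild type replicates 1, 2 or 3 or mutant replicates 2 or 3 (0.0559 to 0.109) and RpS5b without wild type replicates 1 or 2 or mutant replicates 1 or 3 (0.0658 to 0.0811), limma adjusted p in parentheses. Prosalpha4 lost its call without wild type replicate 1 or mutant replicates 1 or 2 (0.0679 to 0.0744), limma adjusted p in parentheses. RpL34a and RpS5b were not called with the arrays centred on either set of spike-in controls.

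Detoxification and redox genes moved in both directions, with single members among the largest changes on the array. Of 36 glutathione S-transferase genes 7 rose and 8 fell, 8 and 9 when adjusted over the list alone. GstD3 fell by 4.97 ± 0.14 and GstE1 by 1.56 ± 0.07, while GstE6 and the microsomal Mgstl rose by 3.69 ± 0.13 and 1.50 ± 0.05 (log2 change ± SE). Of 81 cytochrome P450 genes 11 fell and 2 rose, the same counts when adjusted over the list alone. Over the 19 members kept by the filter on dim probe sets, 10 fell and 2 rose, with a median of -0.23 (limma camera, adjusted p = 0.0692). Cyp4e2, Cyp9c1, Cyp6a14 and Cyp4d2 fell by 2.68 ± 0.11, 2.14 ± 0.06, 1.05 ± 0.10 and 0.72 ± 0.06, and Cyp18a1, which inactivates ecdysone, and Cyp9f2 rose by 0.69 ± 0.17 and 0.47 ± 0.09. Of 24 antioxidant genes 7 fell and 3 rose, 8 and 6 when adjusted over the list alone. The metallothionein gene MtnA changed by -1.47 ± 0.10, the methionine sulfoxide reductase gene SelR by -0.68 ± 0.05, dj-1beta by -0.54 ± 0.05 and the mitochondrial superoxide dismutase gene Sod2 by -0.38 ± 0.05. MsrA and Prx6c rose by 0.44 ± 0.06 and 0.32 ± 0.08. With their probe sets averaged Mgstl read 0.80 and SelR -0.43. The extracellular superoxide dismutase gene Sod3 rose by 0.29 ± 0.06 on its brighter probe set and fell by 0.81 ± 0.05 on the other (adjusted p = 0.0129 and 5.43e-05, limma), so it has no settled direction. Cyp18a1 lost its call without wild type replicates 1 or 2 or mutant replicates 1, 2 or 3 (0.0616 to 0.0936) and Prx6c without wild type replicates 2 or 3 or mutant replicates 1, 2 or 3 (0.0719 to 0.117), limma adjusted p in parentheses. Sod3 lost its call without mutant replicate 2 (0.0556), limma adjusted p in parentheses. Without wild type replicates 1, 2 and 3 and mutant replicates 1, 2 and 3, in that order, 5, 3, 3, 3, 4 and 5 glutathione S-transferase genes were higher and 6, 9, 9, 8, 7 and 7 P450 genes lower.

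Of 12 measured Foxo targets 3 fell, also 3 when adjusted over the list alone: the myostatin relative myo at -2.34 ± 0.10, Sesn at -0.86 ± 0.14 and foxo itself at -0.48 ± 0.07 (log2 change ± SE). Of 7 heat shock genes the small heat shock gene l(2)efl fell by 1.79 ± 0.11 and Hsp60A by 0.28 ± 0.05, the latter not with the arrays centred on spike-in controls, and l(2)efl read -1.13 with its probe sets averaged. Adjusted over the list alone, 2 were lower and 1 higher. Other members, Hsp68 at 1.63 ± 0.78 and stv at 0.86 ± 0.29, were not called (adjusted p = 0.213 and 0.0874, limma), and on the array of wild type replicate 3 Hsp68 read 8.53 against 11.29 and 11.88 on the other wild type arrays. Without wild type replicate 2 stv was called (limma adjusted p = 0.04, and 0.0119 to 0.227 over all alternatives), as it was with either spike-in centring, and Hsp68 with the hybridization spike-ins. None of the glutathione S-transferase, P450, antioxidant, Foxo and heat shock lists passed (limma camera, adjusted p from 0.138 for the P450s to 0.996 for the heat shock list). The median of the heat shock list was 0.37 over the 6 arrays, 0.04 without wild type replicate 3 and 0.59 without wild type replicate 2. The glutathione S-transferase list had a median of 0.01, or -0.03 without wild type replicate 2, a mean of -0.06 and a test direction of lower.

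Several targets of Notch, the receptor that sets the wing margin and the sensory organs, fell in the mutant. Of 10 measured targets 5 fell and none rose, 8 lower when adjusted over the list alone, and the 5 are genes of the Enhancer of split complex. E(spl)m6-BFM changed by -1.02 ± 0.22, E(spl)malpha-BFM by -0.72 ± 0.11, E(spl)m2-BFM by -0.38 ± 0.11, E(spl)m4-BFM by -0.36 ± 0.08 and E(spl)m5-HLH by -0.35 ± 0.07 (log2 change ± SE). The median of the list was -0.37 (limma camera, adjusted p = 0.00263; adjusted p = 0.541 with an estimated correlation). The array of wild type replicate 3 read lowest of the wild type for 9 of the 10, and without it all 10 targets were called lower. Without wild type replicate 1, mutant replicate 1 or mutant replicate 3 the count was 2, and without mutant replicate 2 it was 3. E(spl)m6-BFM lost its call without wild type replicate 1 or mutant replicates 1 or 3 (0.0588 to 0.0753) and E(spl)m4-BFM without wild type replicate 1 or mutant replicates 1, 2 or 3 (0.0501 to 0.08), limma adjusted p in parentheses. E(spl)m2-BFM lost its call without wild type replicates 1 or 2 or mutant replicates 1, 2 or 3 (0.0961 to 0.129), limma adjusted p in parentheses. E(spl)m5-HLH read -0.22 with quantile normalization and was not called (limma adjusted p = 0.0801). Centred on the hybridization spike-in controls the median read -0.19 and 2 targets were lower. Of 48 wing patterning genes 9 fell and 3 rose, 12 and 4 when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.321). The Hedgehog receptor gene ptc changed by -0.65 ± 0.06 and bab1 by -0.66 ± 0.12, and sob, drm and bab2 rose by 0.32 ± 0.05, 0.28 ± 0.05 and 0.27 ± 0.05. Without wild type replicates 1, 2 and 3 and mutant replicates 1, 2 and 3, in that order, 4, 4, 3, 4, 2 and 4 wing patterning genes were lower. None of the 8 measured homeotic genes passed the test, nor any when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.304, with a median of 0.09). Antp was called higher with the trended and robust prior and with the hybridization spike-in centring (limma adjusted p = 0.0387 and 0.0165). The largest levels were those of Antp, at 10.11 ± 0.08 and 10.25 ± 0.04 in wild type and mutant (SD, n = 3 each), and eve. The gene eve read 4.46 ± 0.10 and 4.45 ± 0.06, near the median level of all probe sets, 4.44, and its log2 change was -0.01 ± 0.07 (SE). Only 1 of the 8 lay above the median level on every mutant array, so the lack of calls says little about the other members.

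Of the other histone methylation regulators 6 of 19 measured genes were called, most with small changes. Set8, which methylates histone H4, rose by 1.78 ± 0.12 (log2 change ± SE, adjusted p = 7.18e-05, limma), and JMJD7 by 0.17 ± 0.05. The other 4 calls were lower, Kdm3 at -0.22 ± 0.05, E(z) at -0.22 ± 0.06, ash2 at -0.20 ± 0.05 and Su(var)3-3, the fly LSD1 demethylase gene, at -0.19 ± 0.05. Adjusted over the list alone, 3 were higher and 4 lower, and the list did not pass (limma camera, adjusted p = 0.938, with a median of -0.04, or -0.02 without mutant replicate 3, and a mean of 0.06). Kdm3 lost its call without wild type replicates 1 or 3 or mutant replicate 2 (0.0501 to 0.0743) and E(z) without wild type replicates 1, 2 or 3 or mutant replicates 1 or 2 (0.0852 to 0.122), limma adjusted p in parentheses. ash2 lost its call without wild type replicates 1 or 2 or mutant replicates 1, 2 or 3 (0.0616 to 0.102) and Su(var)3-3 with any 1 of the 6 arrays left out (0.0626 to 0.155), limma adjusted p in parentheses. JMJD7 lost its call with any 1 of the 6 arrays left out (0.0647 to 0.139), limma adjusted p in parentheses. Kdm3, E(z), ash2 and Su(var)3-3 were also not called with either spike-in centring.

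Several genes of the list of JNK and regeneration stress genes rose in the mutant, while scaf and egr fell. Of 16 measured genes 8 rose and 2 fell, 12 and 2 when adjusted over the list alone, with a median of 0.28 (limma camera, adjusted p = 0.000794; adjusted p = 0.541 with an estimated correlation), or 0.41 over the 14 members kept by the filter on dim probe sets. Gadd45 rose to 8.62 ± 0.14 (SD, n = 3), a change of 2.22 ± 0.10 (SE). The transcription factor genes chinmo and Irbp18 rose by 1.38 ± 0.12 and 0.72 ± 0.04. The protease-like gene scaf fell by 1.17 ± 0.09, and egr, the fly TNF gene, changed by -0.32 ± 0.08 and was not called with either spike-in centring, nor with its probe sets averaged (-0.17). egr lost its call without wild type replicates 1, 2 or 3 or mutant replicates 2 or 3 (0.0539 to 0.09) and rad50 without wild type replicates 1, 2 or 3 or mutant replicates 1 or 2 (0.054 to 0.0866), limma adjusted p in parentheses. Of 11 cell death and p53 target genes 3 rose, Irbp by 0.78 ± 0.05, the caspase gene Dronc by 0.73 ± 0.10 and rad50 by 0.21 ± 0.05, and egr, counted here too, fell. That made 5 higher and 1 lower when adjusted over the list alone. This list did not pass (limma camera, adjusted p = 0.321).

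Ecdysone response genes rose more often than they fell. Of 22 measured genes 6 rose and 2 fell, 9 and 2 when adjusted over the list alone, with a median of 0.10 (limma camera, adjusted p = 0.0377; adjusted p = 0.541 with an estimated correlation), or 0.15 without wild type replicate 2 and 0.23 over the 18 members kept by the filter on dim probe sets. The nuclear receptor genes Eip78C and Hr3 rose by 1.58 ± 0.09 and 1.36 ± 0.16, and ImpE3 and ImpE1, known from everting discs, by 1.06 ± 0.10 and 0.76 ± 0.09 (log2 change ± SE), though ImpE1 read 0.44 with its probe sets averaged. The competence factor gene ftz-f1 fell by 1.17 ± 0.14. Edg78E, at -0.18 ± 0.05, was not called with either spike-in centring. Edg78E lost its call with any 1 of the 6 arrays left out (0.062 to 0.151), limma adjusted p in parentheses. The call of the list ended without wild type replicate 1 or mutant replicate 3 (camera, adjusted p = 0.0636 and 0.0935), with quantile normalization (adjusted p = 0.0776) and with the hybridization spike-in centring (adjusted p = 0.0647), with a range of 0.00875 to 0.541 over all alternatives. Of 16 immune effector genes Def rose by 0.97 ± 0.09 and Listericin fell by 2.64 ± 0.26. Mtk and nec, at -0.27 ± 0.06 and -0.31 ± 0.08, were not called with either spike-in centring. Mtk lost its call without wild type replicate 1 or mutant replicates 1 or 2 (0.0584 to 0.0723) and nec without wild type replicates 1, 2 or 3 or mutant replicates 1 or 2 (0.0506 to 0.118), limma adjusted p in parentheses. Adjusted over the list alone the count was also 1 higher and 3 lower, and the list did not pass (camera, adjusted p = 0.604).

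**Figure D3:**
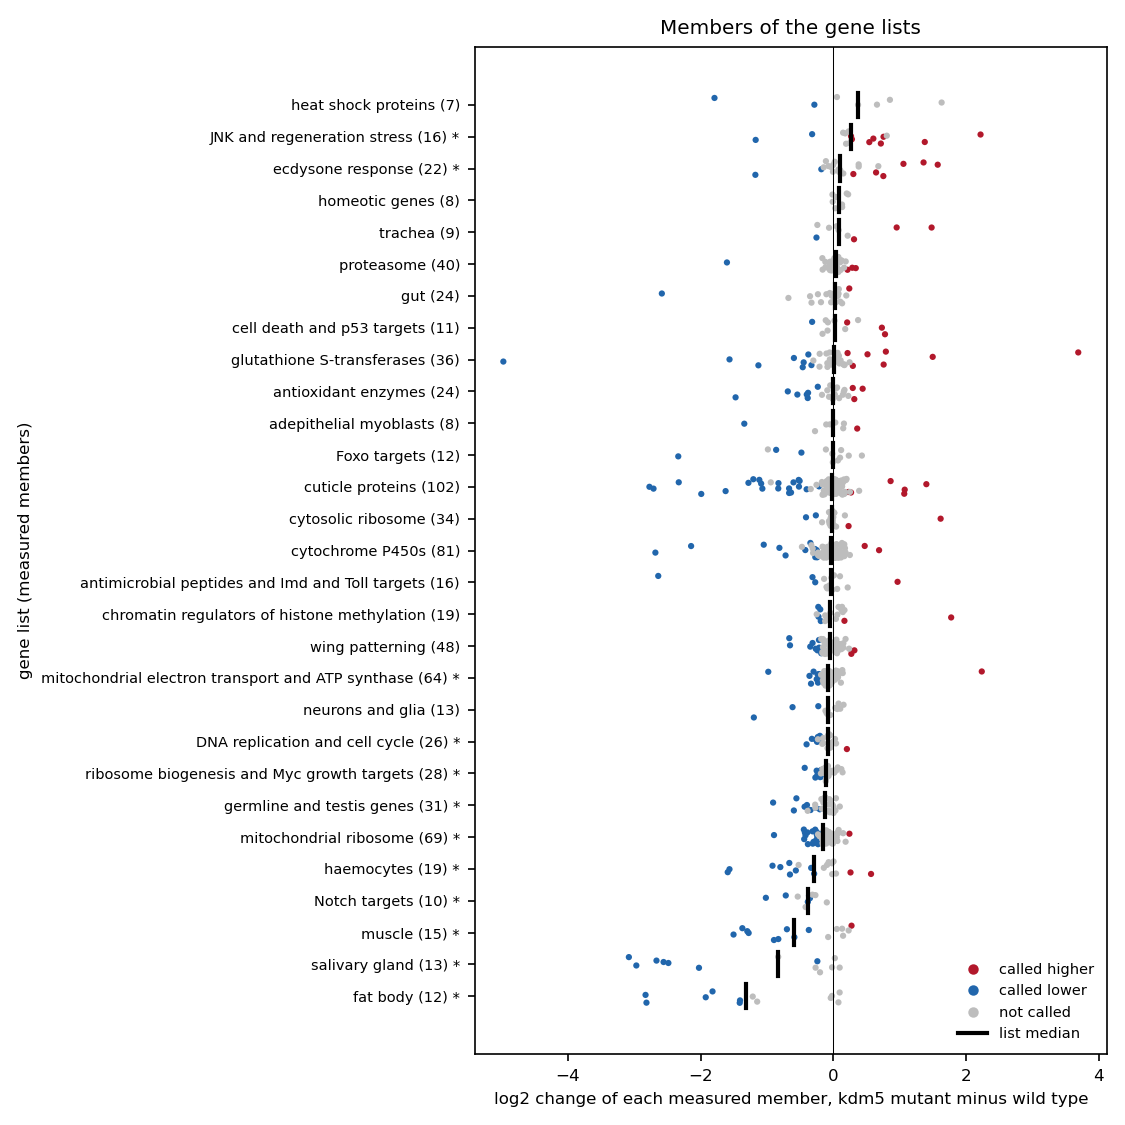
Log2 change, kdm5 mutant minus wild type, of each measured member of the 29 gene lists tested, with the number of members in parentheses; red and blue points were called higher and lower (limma, 3 arrays per group), black bars are list medians, and stars mark lists past an adjusted p of 0.05 with camera's preset correlation. Medians run from -1.31 for fat body to 0.37 for heat shock proteins (0.04 without wild type replicate 3), and no star is kept with an estimated correlation.

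Of 29 lists tested, 12 passed an adjusted p of 0.05 with the preset inter-gene correlation of 0.01, 10 lower and 2 higher in the mutant. With a correlation estimated from the data 0 passed, so a shift of a list as a whole is not established. The fry test gave the 12 lists unadjusted p from 0.000264 (germline and testis) to 0.0361 (Notch targets), in the same directions. Lists that did not pass with camera also had low p (limma fry, unadjusted, 7.93e-05 for trachea and 0.00112 for antioxidant enzymes). The fry result therefore does not establish a shift beyond that of other genes. The adjusted p of 0.541 is shared by lists whose unadjusted camera p ran from 0.021 (germline and testis) to 0.298 (ribosome biogenesis). For the germline and testis list the estimated correlation, -0.009, lay below the preset. Its unadjusted camera p still rose from 0.00121 to 0.021, so correlation alone does not account for the loss. With an estimated correlation camera also refers its statistic to the 4 residual degrees of freedom, which raises p by itself. A call lost in that form is therefore no evidence that the members of a list vary together. Over all named genes 21.7% were called, 9.76% higher and 11.9% lower, which the counts of called members above can be read against. The levels of NimB1, tej, Mst87F, RpS10a, Mal-A1, Prx6c, Mtk, nec, Edg78E and CG13659 lay below the median of all probe sets in both genotypes, and those of bam, myo, Nplp2, bab1 and Listericin in the mutant and of CG31157 in wild type, so the size of these changes depends on the background of the array.

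Genes next to each other on the chromosome changed together at several places. Beside ry, the gene l(3)87Df rose 4.58-fold, and Hsc70-2 and its neighbour CG31157, a few genes away, rose by 3.92 ± 0.09 and 2.10 ± 0.15 (log2 change ± SE). The next measured gene on the far side of l(3)87Df, CtBP, was not called, at -0.15 ± 0.05. CHKov1 and CHKov2 lie side by side and rose by 2.28 ± 0.08 (3.62 with its probe sets averaged) and 4.29 ± 0.17. Farther along, CG31436, CG31370 and CG13659, which adjoin each other, rose by 2.03 ± 0.10, 1.89 ± 0.07 and 1.32 ± 0.13. Most of the measured genes between CG31436 and CHKov1 were not called. Within 4 measured places of Kdm5, Tsp26A fell by 1.27 ± 0.16 while CG9098, H2.0 and ifc rose by 1.16 ± 0.12, 0.56 ± 0.07 and 0.46 ± 0.05. Gene order was taken from assembly GCF_000001215.4 Release 6, and these neighbours were named after their values were seen.

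**Figure D4:**
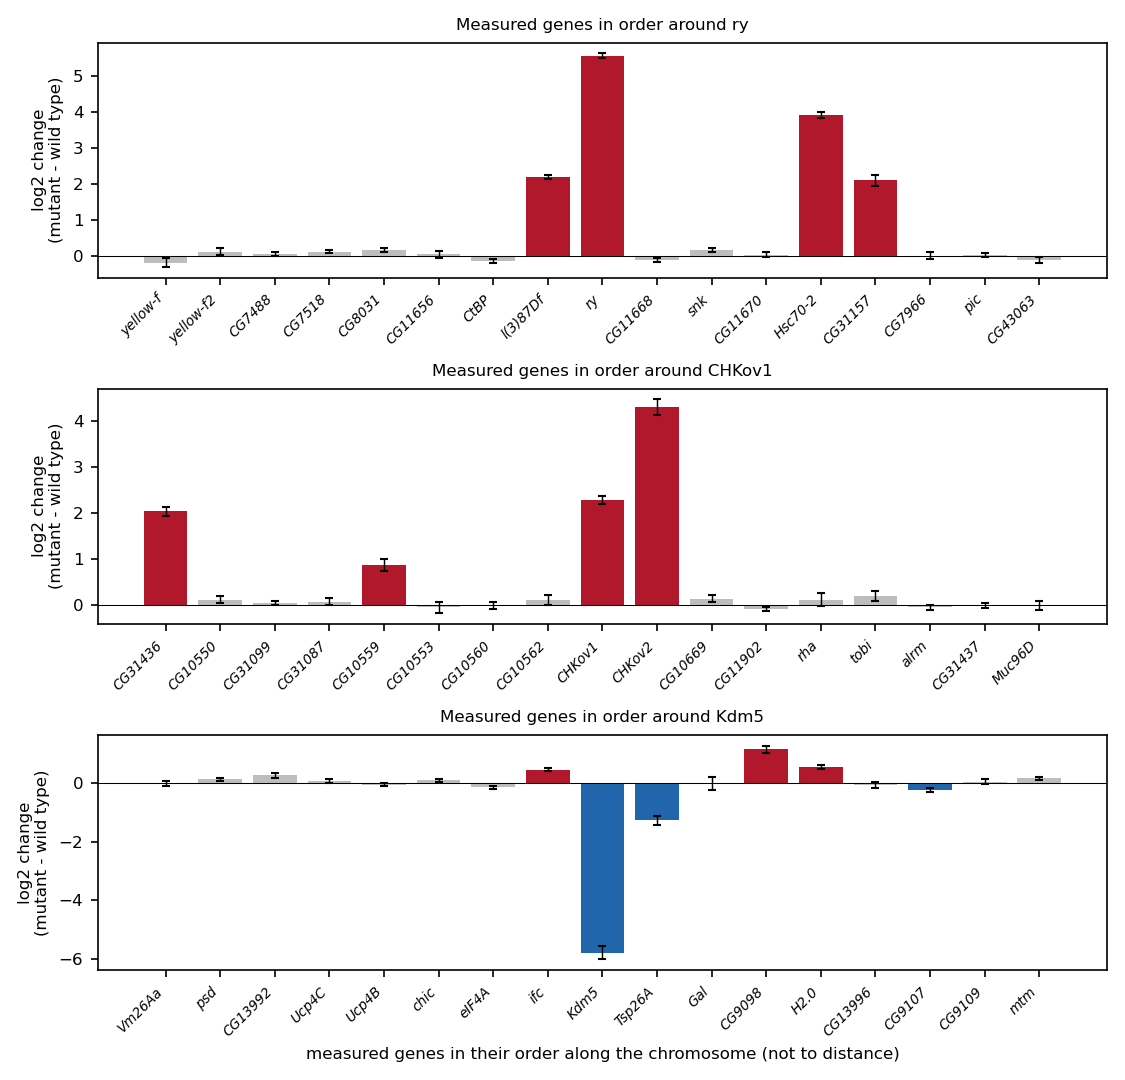
Log2 change, kdm5 mutant minus wild type, of the measured genes in chromosome order around ry, CHKov1 and Kdm5; bars are coefficients with SE from limma (3 arrays per group), red and blue bars were called higher and lower, and spacing is not to distance. Called genes stand among uncalled ones, with ry at 5.56 and CHKov2 at 4.29 beside genes near 0.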

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

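The tests of scaling, of adhering tissue, of a general fall, of stage and of shared haplotypes were chosen after the results were seen; those of probe sets that match several genes, of other splits of the arrays and of gene families were set out before their results were known.

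Several control probe sets outside the comparison differed between genotypes, with every mutant array outside the range of the wild type arrays. The hybridization spike-ins differed by -0.18 in the mutant (10.60 ± 0.03 against 10.78 ± 0.07, SD, n = 3 each) and the 18S rRNA probe sets -0.44 (11.94 ± 0.05 against 12.38 ± 0.07). The 5' and 3' probe sets of Act5C read 0.28 and 0.0535 higher, those of eIF4A -0.20 and -0.12, and the 5' probe set of Gapdh 0.15 higher. For each an exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. The polyadenylated spike-ins differed by -0.08 and the 3' probe set of Gapdh by 0.0762, both with overlapping arrays. Within an array the 3' minus 5' difference of Act5C, eIF4A and Gapdh differed by -0.231, 0.081 and -0.0715 (exact permutation p = 0.1, 0.4 and 0.1), without a common direction.

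Lower calls outnumbered higher calls in the deposited scaling, 1846 against 1593. The share of lower calls was 49.6% with quantile normalization and 50.7% with each array centred on its median, on either side of an even split, so the scaling of the arrays and a true excess of falls cannot be told apart. A first form of this test, which counted a turn under any of 4 scalings, was replaced after its result was seen: the shares of 12.8% and 34.2% with the hybridization and polyadenylated spike-ins follow from the shift those centrings add and decide nothing. Changes of 2-fold or more were lower in 293 of 481 cases as deposited, 263 of 474 with quantile normalization, 290 of 482 with median centring, 255 of 476 with the polyadenylated and 220 of 478 with the hybridization spike-ins. A true difference in RNA per disc cell between genotypes was not tested, and stays open.

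Several salivary gland, fat body, muscle and haemocyte markers were lower in the mutant. A general fall in the share of every other tissue cannot be told apart from falls of single tissues over all members. There the trachea list had a median change of 0.081, within the interquartile range of 2.36 from that of the salivary gland list, -0.83. Over members above the median level in wild type, a form tried later, these medians were 0.134 and -2.52 (interquartile range of the salivary gland list 1.02). In that form the gut, myoblast and neuron medians were 0.0205, -0.009 and -0.117. Keeping members by their wild type level favours genes that fall. With members kept by their mean over the 6 arrays, the neuron median was -0.0279 over 4 members. The trachea, gut, myoblast and salivary gland medians were then the same as before. The trachea, gut, myoblast and neuron lists thus showed no fall of the size of the salivary gland list's, though single members such as LManII and Nplp2 fell. Tracheal markers such as verm, at 9.63 in wild type, were abundant and might not show the loss of a small share. Varying amounts of adhering tissue may account for part of the falls. In deviations from the genotype means, salivary gland markers moved together more than 99.99% of 10000 random lists matched on level (mean correlation 0.628). Muscle markers did so more than 99.98% (0.523), while fat body markers, at 93.16%, decided nothing. The random lists were not matched on spread. Glue genes spread mostly among the wild type arrays, with SDs of 0.90 in wild type and 0.06 in the mutant for Sgs3, and 0.54 and 0.03 for Sgs7. Their correlation thus rests mainly on the wild type arrays. Genes that are regulated together would deviate together too. A difference in developmental stage cannot be told apart from the genotype, since no time course was used here; of the ecdysone list 6 genes were higher and 2, ftz-f1 and Edg78E, lower, which decides nothing, and the effect of the mutation on these tissues themselves stays open as well.

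Neighbouring genes shared a direction among the 2-fold changes in 20 places, against a median of 5 and a maximum of 16 in 10000 random placements of the 348 genes (permutation p = 1e-04, the smallest these placements can give). Probe sets annotated to several genes had been left out beforehand, so the test could use only probe set names ending in _s_at or _x_at. These made up 8.1% among the 37 genes concerned and 11.8% among all 2-fold genes, a difference of -3.67 percentage points. That argues only against an excess of probe sets with such names in the pairs. Pairs such as Sgs7 and Sgs8, Arc1 and Arc2 or CHKov1 and CHKov2 are related genes that could share regulation, and any of the pairs, such as ry with l(3)87Df, might differ between the strains through linked variants carried on the chromosomes of the mutant stock. The labels give no wild type of the mutant's own background. Strain and genotype therefore cannot be told apart, for these 20 pairs or for any other change reported here. An effect of Kdm5 on blocks of genes stays open.

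Of the 10 ways to split the 6 arrays into groups of 3, 1, the real split, gave 3439 calls, and the highest of the others gave 0. So few splits cannot give a share under 0.05. Every other split also puts both genotypes on each side, so the genotype difference adds to its residual spread. Their lack of calls is therefore no measure of how many calls arise by chance.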

How the results depend on the processing

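The 2 spike-in centrings were chosen after the data were seen. Kdm5 kept its direction and its call under every alternative, with log2 changes from -5.98 to -5.50. The count of 3439 calls became 7225 with the arrays centred on the hybridization spike-ins, 6302 higher and 923 lower, and 1029 lower calls were left with the polyadenylated spike-ins; both follow from the shift each centring adds to all probe sets. With 1 array left out, higher calls numbered 1020 to 1281 and lower calls 1300 to 1543, with fewer samples in the fit. Other alternatives over probe sets gave 3430 to 4388 calls, and tests by gene 2925 or 2933; 2-fold calls ran from 445 to 498, and by gene 351 or 327. With the replicate number as a block the count was 2497. Deviations of arrays with the same number correlated at -0.07, -0.03 and -0.18, and those with different numbers at -0.12 to 0.13. No pairing by number was seen, though 3 arrays per group cannot exclude a weak one. Of the 12 lists past the threshold, 0 passed with an estimated correlation. Of 161 called genes named in the text, 33 lost the call with at least 1 array left out (0 moved over 1.5-fold), 27 with the hybridization and 23 with the polyadenylated spike-ins. Sod3 turned to -0.26 with its probe sets averaged, since they differ in direction, and Edg78E to 0.0013 with the hybridization spike-ins. Signal over background is unknown. Changes of 0.25 log2 units were mostly missed in the simulation, where far fewer probe sets changed than were called here. Of the calls in the data, 63.1% were changes under 0.5 log2 units. The alternatives for linear values were not run, as the values are log2.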

Other observations

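The test of gene families was set out before its result was known, and the families named below were named after their values were seen. Genes that share the letters of their symbol were tested as 117 families of at least 6 measured genes. Past the adjusted threshold, 2 combinations of family and direction held more calls than expected (one-sided hypergeometric test, Benjamini-Hochberg over 234 tests). Glue protein genes (Sgs) were lower in 6 of 7 cases against 0.835 expected, adjusted p = 0.00288, and the mitochondrial large ribosomal subunit genes (mRpL) in 16 of 44 against 5.25 expected, adjusted p = 0.00288. This test treats genes as independent, whereas salivary gland markers deviated together (mean correlation 0.628), and neither the salivary gland list nor the mitochondrial ribosome list passed with an estimated correlation (limma camera, adjusted p = 0.541 each). The leucine-rich repeat receptor genes kek1, kek2, kek4 and kek5 were called higher, 4 of 6 kek genes measured, by 0.42 ± 0.06, 0.43 ± 0.11, 0.62 ± 0.07 and 0.58 ± 0.05 (log2 change ± SE), but the family did not pass (adjusted p = 0.0883). The levels of kek2 and kek4 lay below the median of all probe sets in both genotypes, and with their probe sets averaged kek2 and kek5 read 0.27 and 0.26. The gene kek2 lost its call without wild type replicates 1, 2 or 3 or mutant replicate 1 (0.0518 to 0.102), limma adjusted p in parentheses. The 66 Cpr cuticle genes were lower in 17 cases against 7.88 expected, and also did not pass (adjusted p = 0.0883).

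The odorant-binding protein genes Obp56a and Obp56b, which lie side by side, fell by 2.32 ± 0.07 and 3.15 ± 0.13 (log2 change ± SE), beside the falls of Obp99a and Obp99b described among fat body genes. The neighbours gt, a gap gene of the embryo, and tko, a mitochondrial ribosomal protein gene, fell by 1.50 ± 0.18 (0.94 with its probe sets averaged) and 1.54 ± 0.05. Mutant levels of gt and Obp56b lay below that median. Arc2 fell by 1.71 ± 0.12 beside Arc1, and CG17107 by 1.45 ± 0.14 beside CG17105.

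The wild type arrays differed from each other in ways that the mutant arrays did not. On the array of wild type replicate 3, Hsp68 read 8.53, Hsp26 11.81, stv 9.36 and DnaJ-1 11.65, against 11.29 and 11.88, 13.15 and 13.31, 10.28 and 10.58, and 12.64 and 12.79 on those of replicates 1 and 2. The mutant arrays read 12.07, 12.09 and 12.44 for Hsp68. Glue genes were highest on the array of wild type replicate 1, where Sgs1 read 6.25 against 4.52 and 4.89, and the fat body gene Obp44a read 7.30 and 7.39 on those of replicates 1 and 3 against 4.43 on that of replicate 2.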
